A study of Mus musculus with 6 samples.

How the data were processed

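DNA methylation was measured by tagmentation-based whole-genome bisulfite sequencing, a method in which a transposase fragments and tags a small amount of DNA before bisulfite treatment turns unmethylated cytosines into uracil. Per the labels' protocols, 30 ng of genomic DNA from sorted lung endothelial cells was used per sample, and several libraries per sample were sequenced as 100 bp paired reads on a HiSeq2000 instrument. Per the submitters' processing notes, BWA 0.7.8 and the mouse build mm10 were used. The CpG caller, any filter on coverage, any smoothing step and the way CpG values were averaged over windows are not given in the sources used here.

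The deposited table gives, as a fraction from 0 to 1, the authors' mean methylation level of each sample in 1684140 windows of 1000 bp on the 19 autosomes. It gives neither read coverage nor the number of CpG sites, so the depth of each sample is unknown, no counting error could be attached to a value, and every window was weighted equally. Fractions were multiplied by 100 and are given as percent, with differences in percentage points. Windows with a value in all 6 samples were kept (1683697), which left out those behind the 1685 missing values. The values are not plain ratios of read counts: 16326 of them lie above 0 and under 1e-08 percent. The deviations of adjacent windows from their means over samples correlated with r between 0.392 and 0.405 across windows, so neighbouring windows are not independent. Windows with a value under 0.01% or above 99.99% in at least 1 sample are called windows with extreme values below.

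The samples fall into a group of 3 titled mAdu and a group of 3 titled aged. The series' design names the ages 8 and 18 months without tying them to sample titles. The group titled aged was taken as the 18-month group and mAdu as the 8-month group. The labels do not say whether the samples of a group came from separate animals. The p-values of tests that compare samples therefore measure the spread between these samples, which may be technical. Tests named below that compare genes with other genes, camera among them, rest on the spread between genes as well or instead.

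Gene positions came from a RefSeq table of GRCm38.p6, whose coordinates are those of mm10. That table gives gene spans but no strand, exons or sequence. Promoters were therefore replaced by the less methylated of the ends of each gene, measured from 1000 bp outside to 500 bp inside the gene edge and chosen by the mean over all 6 samples. This end need not hold the transcription start. Exon, intron and CpG island classes were replaced by windows within 1000 bp of an edge of a protein-coding gene, other windows inside such genes, and windows outside them. A gene body ran from 500 bp inside each edge and needed at least 3 windows. The value of a region is the unweighted mean of the windows that overlap it, which at gene ends is often 1 to 3 windows. Of 334 listed genes, 333 were found in the gene table and 329 lay on autosomes.

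Single values per sample were compared by an exact two-sided permutation test, which for 3 samples against 3 cannot give a p below 0.1. Windows, non-overlapping 100-kb intervals with at least 10 windows, gene ends and gene bodies were tested with limma 3.58.1 in R 4.3.3 on the percent scale, with group as the only term, a variance trend, and Benjamini-Hochberg adjustment at 0.05. Intervals of differences are 95% intervals of that model. Adjusted p-values given for windows, intervals and genes are limma's. Gene lists were tested at gene ends and gene bodies with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation. They were also tested with fry, which asks whether the genes of a list move on balance in 1 direction and, in its mixed form, whether they change in either direction. List members were adjusted over all genes tested and also over the list alone.

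The 18 lists were endothelial identity genes, lung capillary genes, arterial, venous and lymphatic genes, angiogenic signalling, TGF-beta and BMP signalling with mesenchymal transition, shear stress and quiescence, senescence and its secretory phenotype, inflammation and interferon response, Hox genes, developmental transcription factors, the DNA methylation machinery, imprinted genes, germline genes, genes named for age-related methylation, Wnt signalling, and markers of epithelial, haematopoietic and mesenchymal cells. For each kind of feature, the rule for named items took the 10 passing features with the largest difference in each direction and without overlap of the groups. Where fewer than 5 passed in a direction, it took the 5 with the smallest p and named them as not passing. It added up to 4 members of each list with the smallest p in each region, and always H19, Snrpn, Peg3, Kcnq1ot1, Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2 and Tet3. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined. Levels of cell type markers were compared afterwards by a permutation test across genes with 100000 resamples, adjusted over its 6 comparisons, and levels of lists were set beside 10000 random lists of equal size, matched at gene bodies on the number of windows.

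The tests were tried on simulated data, made by permuting the 6 values of each feature and shifting 200 features by each of 5, 10, 20 and 40 points. At 10 points limma recovered 91% of shifted 100-kb intervals, 72% of gene ends, 95.5% of gene bodies and 1.5% of single windows. At 40 points it recovered 66% of single windows. All shifts were adjusted together, which eases the threshold, so these shares overstate what would be recovered of a few isolated changes. Limma also called 369 windows, 44 intervals, 28 gene ends and 40 gene bodies that had not been shifted. The eased threshold adds to these counts too, so they are not the counts to expect where nothing is shifted. Groupings of the 6 real samples that mix the ages, described below, gave 289 to 438 windows. They gave at most 2 intervals, 3 gene ends and 3 gene bodies. A call on a single window is therefore weak evidence of a difference, and calls of the other kinds can be false too. For random lists of 20 genes shifted by 1 point, camera gave an unadjusted p under 0.05 for 85% at gene ends and 100% at gene bodies. For lists that were not shifted the shares were 3% and 1%. Permuting each gene separately removed the correlation between genes, so these shares need not hold for lists whose genes correlate.

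The alternatives were a logit scale with an offset of 0.01, centring of each sample, other variance priors, the replicate number as a block, each sample left out in turn, 1-Mb intervals, other widths of the gene end, class limits of 10% and 90%, medians over windows, and the estimated correlation. Removal of the windows with extreme values, the more methylated gene end, and leaving out samples in the list tests were added after seeing the data. Sex chromosomes were not analysed here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.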

Results

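Genome-wide DNA methylation was compared in endothelial cells sorted by flow cytometry from the lungs of wild-type mice at 8 months (mAdu, 3 samples) and 18 months (aged, 3 samples). The comparison asks how the methylation landscape of the lung endothelium differs between these ages. The values are mean methylation levels of windows of 1000 bp on the 19 autosomes, and 1683697 windows had a value in all 6 samples. Between 100 and 443 windows per sample lacked a value. The read depth is unknown, so precision was judged from the spread between samples. Values are means ± SD over the 3 samples of a group, and positions are on mm10.

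Lung endothelial genomes of both ages carried closely similar amounts of methylation. The mean level was 73.5% ± 0.152 in mAdu and 73.4% ± 0.317 in aged samples, a difference of -0.114 points that was smaller than the spread within the aged group (exact permutation p = 0.7). Single samples lay at 73.6%, 73.5% and 73.3% in mAdu and at 73.3%, 73.1% and 73.7% in aged. Windows under 20% methylation made up 3.46% of the autosomal windows with a value in all samples in mAdu and 3.48% in aged. Windows above 80% made up 45.4% and 45.1%, and those between made up 51.1% and 51.4% (exact permutation p between 0.4 and 0.7). Without aged replicate 2 the difference of the mean level was 0.017 points, so its direction rests on that sample.

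**Figure D1:**
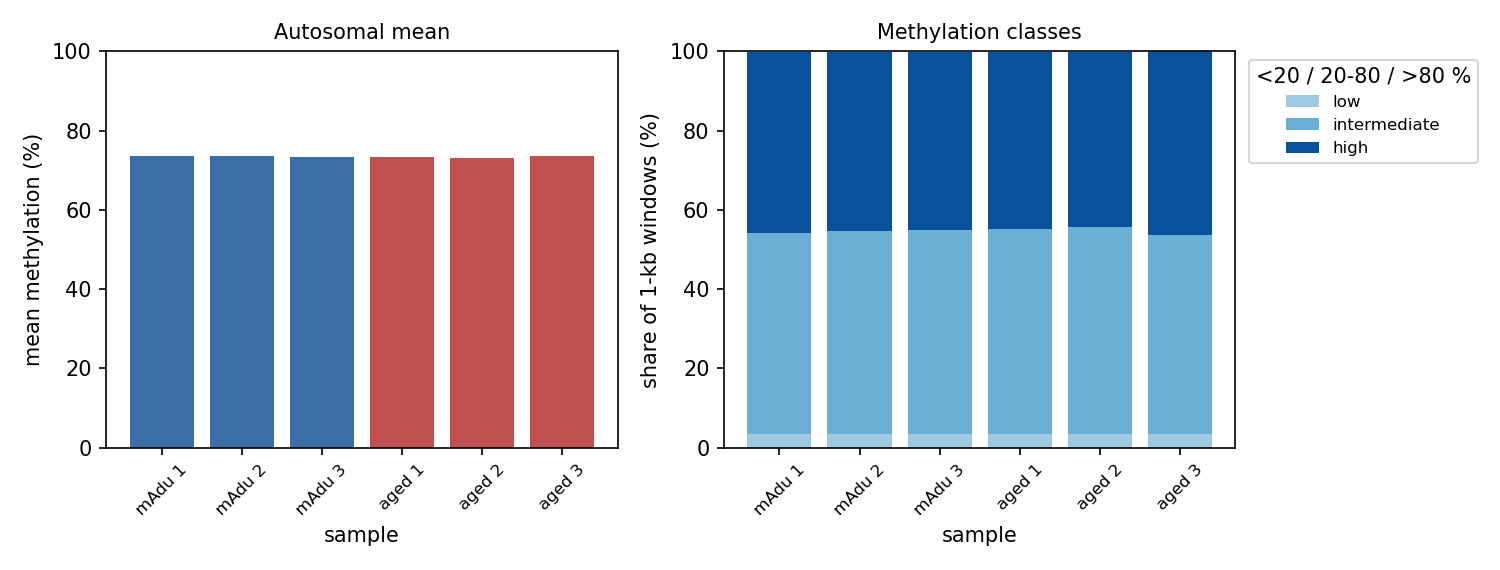
Mean methylation over autosomal windows (left, percent) and share of windows with low, intermediate and high methylation (right, percent) in each of the 6 samples. Means lie between 73.1% and 73.7%, and the groups overlap in each class.

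Lowly methylated windows, grouped by their mean over all samples, had a level of 7.75% in both groups. Intermediate windows lay at 65.7% in mAdu and 65.5% in aged, and highly methylated windows at 87.3% and 87.2%. Windows near the edges of protein-coding genes were the least methylated annotation class, at 56.4% ± 0.134 in mAdu and 56.3% ± 0.187 in aged. Gene interiors lay at 76% ± 0.144 and 75.9% ± 0.272, and windows outside genes at 73.3% ± 0.163 and 73.1% ± 0.371. Chromosome 7 had the lowest level, 71.1% ± 0.18 in mAdu and 70.9% ± 0.252 in aged, and the largest differences by autosome were -0.254 points on chromosome 4 and -0.249 on chromosome 7. The aged mean was the lower on 19 of 19 autosomes, with exact permutation p between 0.3 and 0.9 (0.894 to 0.9 after adjustment over the autosomes). No class differed beyond the spread between samples (exact permutation p between 0.6 and 1). The count of 19 was 6 without aged replicate 2 and 12 without mAdu replicate 1, and without aged replicate 2 the differences at gene edges, in interiors and outside genes were 0.0122, 0.0295 and 0.00723 points. Without mAdu replicate 1 those at gene edges and in interiors were 0.0253 and 0.00639 points, and without aged replicate 1 that at gene edges was 0.00557.

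Endothelial genes stood out from genes of other lung cell types by their low methylation, at both ages. Gene ends of 20 endothelial identity genes averaged 20.8% ± 16.2 (SD over genes), against 45.6% for epithelial, 58.4% for haematopoietic and 36.5% for mesenchymal markers. Their gene bodies averaged 47.1%, against 68%, 69% and 67.9%. This comparison across genes was chosen after seeing the data and covers all 6 samples, and genes are not independent replicates. Two-sided permutation p-values were 0.00032, 1e-05 (the smallest that 100000 resamples can give) and 0.0186 at gene ends and 0.00342, 0.00338 and 0.00596 at gene bodies. After adjustment over the 6 comparisons the permutation p-values were 0.00096, 6e-05 and 0.0186 at gene ends and 0.00513, 0.00513 and 0.00715 at gene bodies. Endothelial bodies ranged from 4.3% to 78%, with an SD of 24 over 18 genes, and that of Vwf, the von Willebrand factor, was at 77.3% in mAdu and 75.8% in aged, within the range of markers of other cell types. The body of Egfl7, a secreted endothelial regulator of vessel formation, was at 6.17% in mAdu and 5.83% in aged. The body of Sox17, an arterial transcription factor, was at 4.89% and 3.72%, and that of Cdh5, the endothelial cadherin, at 39.9% and 40.5%. Pecam1, an adhesion molecule of endothelial junctions, had 39.3% and 40.4% over its body, and the end of Cldn5, a tight junction gene, 0.992% and 0.829%. By contrast the body of Epcam, an epithelial adhesion molecule, was at 70.2% and 70.5%, that of Sftpb, a surfactant protein, at 75.4% and 76.1%, and that of Ptprc, a leukocyte surface phosphatase, at 74% and 74.6%. Col1a1, a fibroblast collagen, was at 55.2% and 55.4%.

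**Figure D2:**
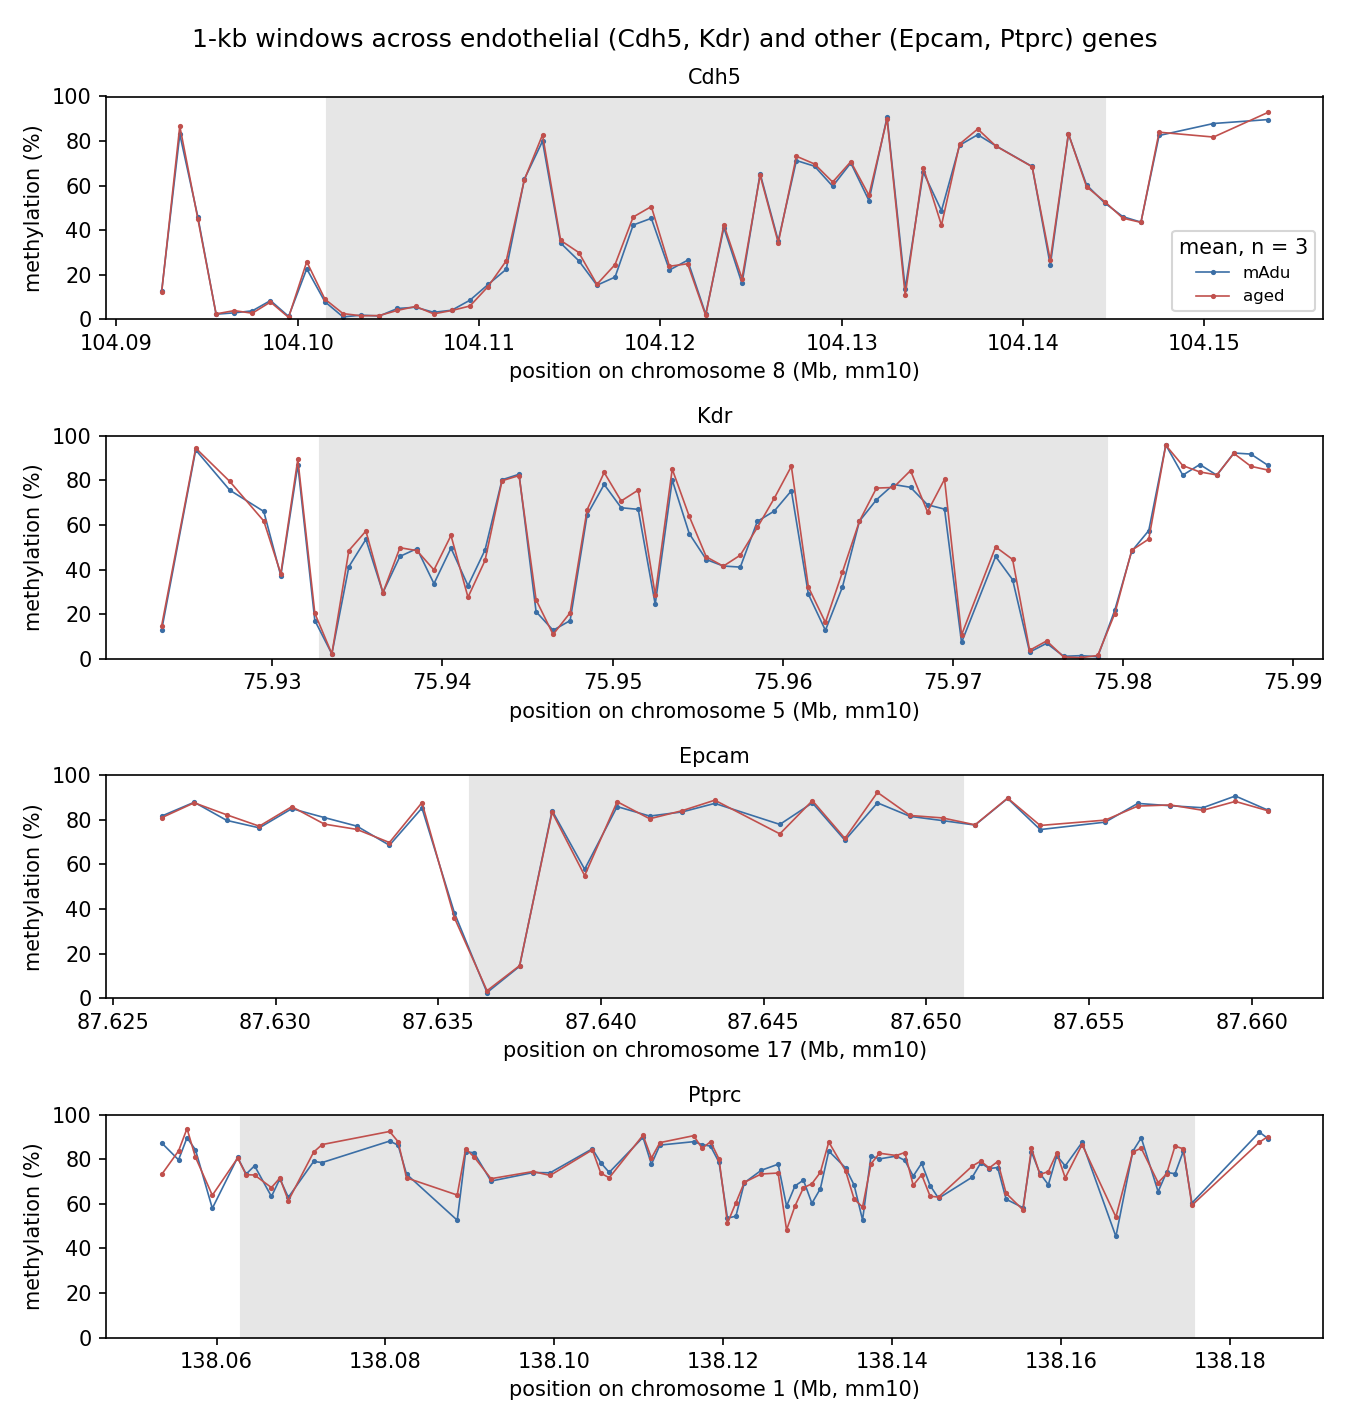
Methylation (percent) of 1-kb windows against mm10 position (Mb) across Cdh5, Kdr, Epcam and Ptprc, with the gene span shaded and a line for the mean of each group. The bodies of Cdh5 and Kdr average 39.9% and 43.8% in mAdu and those of Epcam and Ptprc 70.2% and 74%, and the lines of both groups run close together.

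Among 100-kb intervals without extreme values, those with the lowest levels included the Hox clusters; no test of a shared theme was run. The interval from Hoxc13 to Hoxc6 (chromosome 15, 102900001 to 103000000) was the lowest, at 8.69% ± 0.109 in mAdu and 8.58% ± 0.333 in aged. The Hoxa interval (chromosome 6, 52200001 to 52300000) followed with 28.9% and 29.5%, and the Zic1 and Zic4 interval (chromosome 9, 91300001 to 91400000) with 30.2% and 29.8%. Further low intervals held Hoxb9 to Hoxb6 (34.3% and 34.7%), the Hoxd genes from Hoxd13 (36.4% in both), Tfap2b (37.4% and 36.9%), a histone gene cluster on chromosome 13 (38.3% and 38.5%), Rhcg (38.6% and 38.9%), Six3 with Six2 (38.5% and 39.2%), Uncx (41.9% and 42.2%) and Sptbn1 (41.7% and 43%). The interval of Epas1, a hypoxia-inducible transcription factor abundant in endothelium (chromosome 17, 86700001 to 86800000), lay at 43% ± 0.444 and 43.4% ± 0.276. Hox genes had a median level of 4.41% at gene ends and 11.4% over bodies, and developmental transcription factors 3.53% and 12.8%, where random lists of equal size had medians of 33.3% and 67.6%, and 33.4% and 71.3%.

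**Figure D3:**
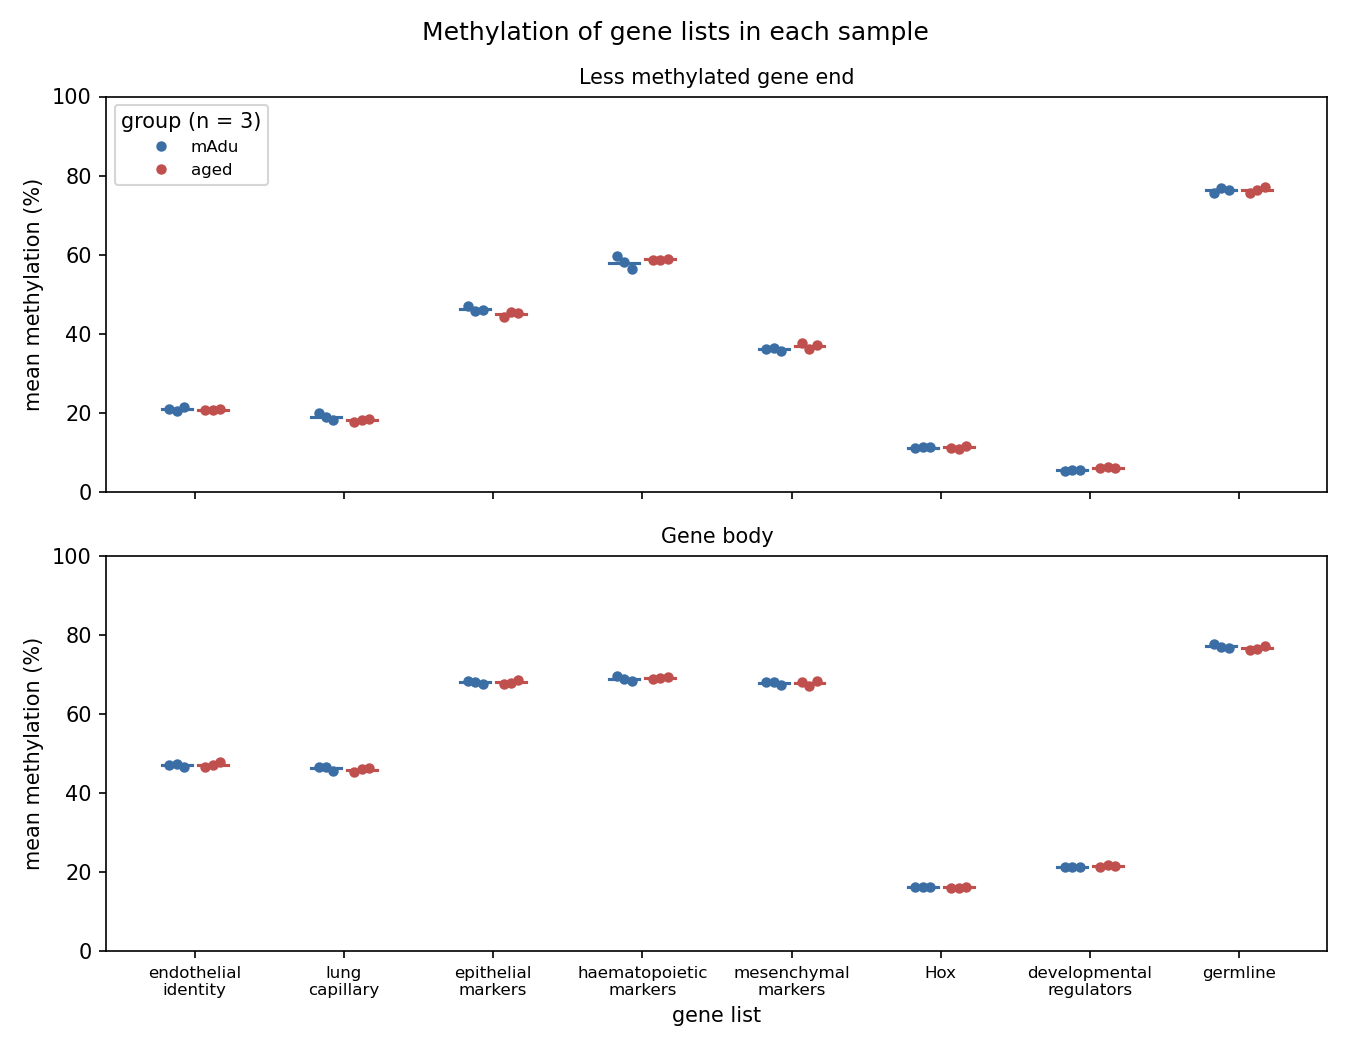
Mean methylation (percent) of 8 gene lists in each sample (points) with group means (lines), at the less methylated gene end (top) and over the gene body (bottom). Endothelial identity genes lie near 20.8% and 47.1%, below the markers of the other cell types, and the ages lie close together.

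No 100-kb interval passed with age: limma called 0 of 24009, and 1095 (4.56%) had an unadjusted p under 0.05. The smallest adjusted p was 0.379. The interval of Arhgap8 (chromosome 15, 84700001 to 84800000) was at 70.7% in mAdu and 74.1% in aged, and that of Chordc1 (chromosome 9, 18200001 to 18300000) at 69.9% and 62.9%, both with an adjusted p of 0.379. The 95% interval of the difference lay within 5 points of 0 for 87.7% of intervals. Without aged replicate 1, 1 interval passed.

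Single windows that passed mostly differed by a large part of the scale. Of 1683697 windows, 355 passed, 150 higher and 205 lower in aged, with a median difference of 90.8 points in size and a smallest of 19.3. Windows unmethylated in mAdu and fully methylated in aged lay near Pramel44 (chromosome 5, 94576001 to 94577000), 50525 bp from the semaphorin and VEGF co-receptor gene Nrp1 (chromosome 8, 128556001 to 128557000), near Cyp3a16, a cytochrome P450 (chromosome 5, 145484001 to 145485000 and 145486001 to 145487000), and near the major urinary protein gene Mup10 (chromosome 4, 60613001 to 60614000 and 60556001 to 60557000). Others had Rxylt1, Kcnh7, Cdc42ep5 or the T cell co-receptor gene Cd28 as their nearest gene. Windows with the opposite change lay near Nat8f2 (chromosome 6, 85872001 to 85873000), near the receptor kinase gene Alk (chromosome 17, 72630001 to 72632000, a pair of windows) and near Gm10681 (chromosome 3, 98570001 to 98571000). The nearest genes of the rest were Bpnt2, Nfib, Wls, Chordc1, Iftap and Plxdc2, up to 838779 bp away. Each of these 20 windows had an adjusted p of 5.88e-05 and an extreme value in at least 3 samples. At an unadjusted p under 0.05 there were 78563 windows (4.67%). The groups did not overlap in 169019 windows, 10% of all, which is the 10% that chance gives. Of the 355 windows, 288 held an extreme value and 67 did not, and 59 passed when all such windows were removed. Leaving out any single sample gave between 680 and 998, and the larger direction turned: higher windows were 42.3% of calls with all samples, 60.8% to 63.6% without any 1 mAdu replicate and 25.5% to 32.9% without any 1 aged replicate.

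At gene ends, Gm45978 (chromosome 7, 29619477 to 29622580), a predicted gene, was the only call. Its end rose from 49.7% ± 3.38 to 91.7% ± 4.67, by 42 points (SE 2.87, adjusted p = 0.0467), over 2 windows and without overlap of the groups. Of these windows, the 1 from 29619001 to 29620000 passed by itself, rising 82.7 points (adjusted p = 0.0286), so the call rests mostly on it. Gm45978 was 1 of 19095 gene ends, and 951 had an unadjusted p under 0.05. The groups did not overlap in 1943 ends (10.2%, where chance gives 10%). Ends that did not pass but had the next smallest p in this direction were those of Gm40365, Gm20172, Sfmbt2 and Gm11239. Sfmbt2, a Polycomb-related gene, was at 3.6% ± 0.232 in mAdu and 6.05% ± 0.214 in aged (adjusted p = 0.89). In the other direction they were Gm9265, Gm10476, Aplnr, Gm8271 and Gm52363, with adjusted p between 0.403 and 0.89. The end of Gm9265 was at 89.3% and 31.2% and that of Gm10476 at 48.9% and 30.3%. Windows with extreme values lay in the ends of Gm40365, Gm11239, Gm9265 and Gm8271. The call of Gm45978 was lost without any of mAdu replicates 1, 2 and 3 or aged replicates 1 and 2 (adjusted p from 0.0545 to 0.599), on the logit scale, without the variance trend and at both other widths of the gene end (adjusted p from 0.0924 to 0.949). Over all alternatives its adjusted p ranged from 0.00717 to 0.949.

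Over gene bodies, Arhgap8 (chromosome 15, 84720034 to 84772857) rose from 67.5% ± 0.372 to 74.1% ± 0.122 (6.61 points, SE 0.404, adjusted p = 0.0238). The bodies of the predicted genes Gm5891 (chromosome 7, 21909434 to 21921291) and Gm10573 (chromosome 4, 122300878 to 122313819) fell by 89 points (adjusted p = 0.0238) and by 55.1 points (adjusted p = 0.0342). The groups did not overlap in any of these bodies. These were the 3 calls among 17538 bodies, of which 873 had an unadjusted p under 0.05. Extreme values lay in 5 of 53 windows of Arhgap8, in 3 of 3 of Gm5891 and in 5 of 9 of Gm10573. Those of Arhgap8 were the windows from 84748001 to 84753000, and without them its difference was 1.2 points (adjusted p = 0.984). The cytokine gene Il10 did not pass, with 58.3% ± 0.678 in mAdu and 63.4% ± 0.722 in aged (adjusted p = 0.558). Nor did Mrgprx1 (61% and 67%), Krt6a (77.8% and 80.3%) and Dusp19 (81.8% and 84.4%). In the other direction Olfm5 (74.7% and 70.5%), Prl2b1 (78.8% and 74.3%) and Gm10324 (91.7% and 19.7%, with extreme values in 8 of 8 windows) did not pass. The 95% interval lay within 5 points of 0 for 91.7% of bodies. The count of 3 was 0 without mAdu replicate 2 or aged replicate 2, 1 without mAdu replicate 3 or aged replicate 1, and 0 without windows of extreme values. Arhgap8 missed the threshold without each of the 6 samples (adjusted p from 0.0719 to 0.198), Gm5891 without each but mAdu replicate 1 and Gm10573 without each but aged replicate 3, and over all alternatives adjusted p ranged from 0.0238 to 0.984, from 0.00828 to 0.849 and from 0.0211 to 0.602.

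Bodies of inflammation and interferon genes were on average less methylated in aged samples, and this was the only list that camera called at gene bodies. Camera gave p = 0.000276, adjusted p = 0.00497, and adjusted p = 0.32 with an estimated correlation. Fry, asked for a shift in 1 direction, gave adjusted p = 0.134 and did not call the list. Of 15 measured bodies 12 were lower in aged, and the mean level was 60.3% ± 0.233 in mAdu and 58.9% ± 0.28 in aged. The mean change was -1.34 points and the median -1.11, and each aged sample lay below each mAdu sample. Chance separates the groups in this way, in either direction, in 10% of cases. List means also separated fully for angiogenic ends and bodies, and for ends of developmental, age-related and epithelial genes. Cd74, the invariant chain of antigen presentation, was at 78.4% ± 1.9 in mAdu and 73.8% ± 0.84 in aged. Irf1, an interferon regulatory factor, was at 36.1% and 33.8%, Nfkbia, an inhibitor of NF-kappa B, at 14.4% and 12.8%, and the interferon-induced Ifit1 at 69% and 65.2%. No member passed, with a smallest adjusted p of 0.0555 when adjusted over the list alone. At gene ends 11 of 18 were higher and 7 lower, and camera gave adjusted p = 0.994. Bodies of haematopoietic markers, whose cells also express genes of this list such as Cd74, had a mean difference of 0.227 points. The list passed without each of the 6 samples in turn (adjusted p from 0.00251 to 0.0392).

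Ends of developmental transcription factors were slightly more methylated in aged samples without passing. Of 39 ends 28 were higher, with a mean of 5.39% ± 0.0701 in mAdu and 6.05% ± 0.254 in aged. Camera gave adjusted p = 0.119, and adjusted p = 0.565 with an estimated correlation. The end of Lhx2 was at 4.8% ± 0.183 and 10.6% ± 2.93, that of Pax2 at 11.8% and 14.9% and that of Neurod1 at 8.83% and 12.9%. Over bodies 23 of 38 were higher (0.314 points, camera adjusted p = 0.152), with Pax9 at 30.9% and 32.7%. Genes named for age-related methylation were higher at 9 of 11 ends, by 0.927 points (camera adjusted p = 0.207), with Klf14 at 5.6% and 8.21%, and at 8 of 12 bodies (0.311 points, camera adjusted p = 0.376). Hox genes had 20 of 37 ends higher (0.0253 points, camera adjusted p = 0.692), with Hoxb1 at 31.5% and 35.8%. Of Hox bodies 13 of 27 were higher (-0.117 points, camera adjusted p = 0.891), among them Hoxd11 at 4.76% and 6.01%, while Hoxa6 was at 43% and 38.5%.

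Among the lung capillary, angiogenic and Wnt lists none passed, and a single gene, Aplnr, passed over the list alone; the other genes given here did not pass. Aplnr, the receptor for apelin and a gene of general capillary cells (chromosome 2, 85136360 to 85139923), fell at its end from 22.8% ± 3.24 to 11.9% ± 0.487, by 10.8 points (SE 1.56). Adjusted over the list alone its p was 0.00452 in the lung capillary list and the same in the angiogenic list, and over all genes 0.89. Its body was at 19.7% ± 3.07 and 11.6% ± 2.28. Within 10 kb of the gene 15 of 16 windows were lower in aged and none held an extreme value, but the locus was picked for its small p, the windows include its end and neighbours correlate, so this count tests nothing. Its end is covered by 1 window. Lung capillary genes had 7 of 17 ends higher (-0.939 points, camera adjusted p = 0.692) and 5 of 14 bodies higher (-0.354 points, camera adjusted p = 0.999). Ednrb, the endothelin receptor of aerocytes, was at 56.5% and 60.6% over its body, Emp2 at 57.4% and 60.7% and Prx at 59.5% and 61.4%, and the end of Fibin was at 16.2% and 19.2%. Angiogenic signalling genes were lower at 12 of 17 bodies (-0.922 points, camera adjusted p = 0.102) and 9 of 17 ends (-0.659 points, camera adjusted p = 0.692). Among them the body of the Notch ligand Jag1 was at 67.9% and 66%. Wnt genes were lower at 17 of 20 bodies (-0.394 points, camera adjusted p = 0.131) and 12 of 20 ends (-0.229 points, camera adjusted p = 0.692), with the body of the receptor Fzd4 at 15.4% and 13.2%.

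**Figure D4:**
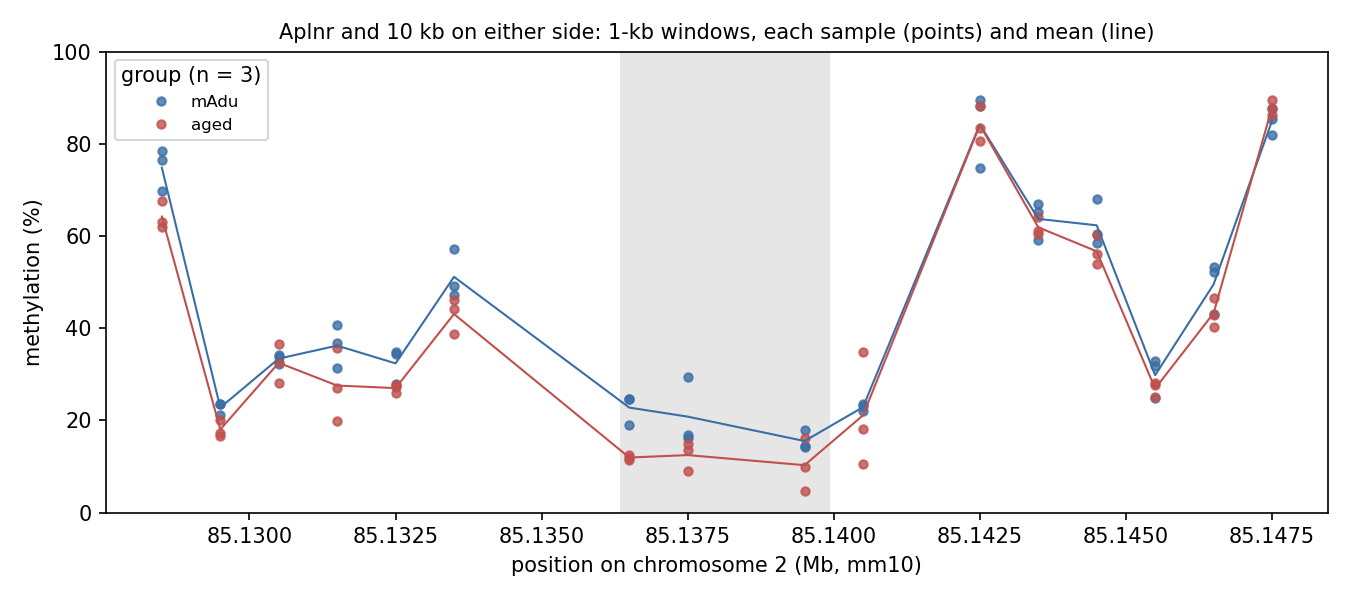
Methylation (percent) of 1-kb windows against position on chromosome 2 (Mb, mm10) across Aplnr (shaded) and 10 kb on either side, with points for the samples and lines for group means. Aged samples have the lower mean in 15 of the 16 windows.

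**Figure D5:**
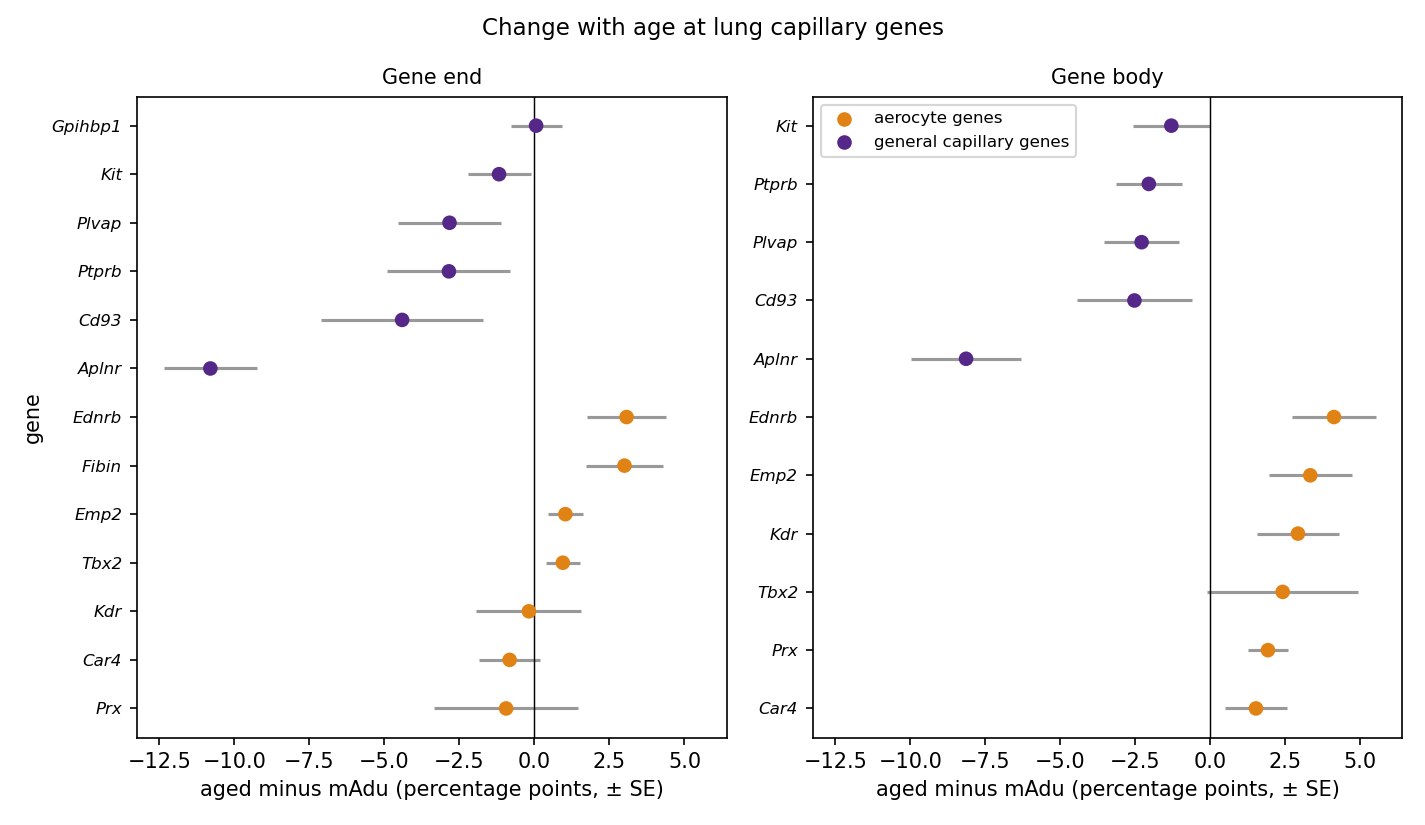
Difference in methylation, aged minus mAdu (percentage points, bars show the SE), at the ends and bodies of aerocyte genes (orange) and general capillary genes (purple), 3 samples per group. The split into these classes was made after the values were seen. It left out Sema3c, Hpgd, Icam2, Calcrl and Ramp2 of the lung capillary list and added Kdr. Bodies of 6 of 6 aerocyte genes are higher and of 5 of 5 general capillary genes lower. By contrast, ends of Prx, Car4 and Kdr are lower and that of Gpihbp1 is higher.

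The other endothelial lists moved little. Endothelial identity genes had 12 of 20 ends lower (-0.176 points, camera adjusted p = 0.915) and 10 of 18 bodies lower (0.101 points on average, camera adjusted p = 0.819). Kdr, the main VEGF receptor, was at 43.8% ± 2.51 and 46.7% ± 1.1 over its body. Arterial, venous and lymphatic genes had 9 of 16 ends lower, with a mean change of -4.15 points and a median of -0.115 (camera adjusted p = 0.692). The mean rests on the end of Ccl21a, at 94.5% ± 9.48 and 33.3% ± 57.7, where 3 of 3 windows held extreme values. The end of Lyve1, a lymphatic receptor for hyaluronan, was at 25.8% and 20.6%, and 10 of 15 bodies of the list were lower (-0.686 points, camera adjusted p = 0.303). TGF-beta and BMP genes had 12 of 19 ends higher (0.153 points, camera adjusted p = 0.705) and 12 of 15 bodies lower (-0.309 points, camera adjusted p = 0.324), with Bmpr2 at 53.3% and 54.9%. Shear stress and quiescence genes had 7 of 14 ends higher (-0.292 points, camera adjusted p = 0.692) and 8 of 14 bodies lower (-0.0445 points, camera adjusted p = 0.847), with Cdkn1c at 43.4% and 46.6%.

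Among senescence genes the body of Il6, an inflammatory cytokine, rose from 69.5% ± 1.34 to 74.4% ± 1.2, by 4.97 points (limma adjusted p = 0.0202 when adjusted over the list alone, adjusted p = 0.952 over all genes). The body of Cdkn2b, a cell cycle inhibitor, was at 36.5% and 31.6% and that of the chemokine gene Ccl5 at 82% and 80.5%, neither of which passed. The list had 9 of 16 ends higher (-0.0118 points, camera adjusted p = 0.958) and 8 of 14 bodies higher (-0.0964 points, camera adjusted p = 0.717). Il6 lost its call without mAdu replicate 2 and without aged replicates 1 and 2 (adjusted over the list alone, to 0.0505, 0.0908 and 0.0788).

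Markers of other cell types that a sort could leave behind did not pass in either region. Epithelial markers had 10 of 14 ends lower (-1.28 points, camera adjusted p = 0.311), with Sftpd at 74.3% and 68.5% and Lamp3 at 66.3% and 58.5%, and 8 of 14 bodies higher (-0.00209 points, camera adjusted p = 0.837), with Ager at 54.7% and 52.5%. Haematopoietic markers had 10 of 15 ends higher (0.774 points, camera adjusted p = 0.692) and 5 of 13 bodies higher (0.227 points, camera adjusted p = 0.678), with Itgam at 75.4% and 76.6%. Mesenchymal markers had 10 of 14 ends higher (0.847 points, camera adjusted p = 0.311) and 6 of 14 bodies higher (0.0611 points, camera adjusted p = 0.857), with Lum at 75.6% and 78.1% and Dcn at 72.9% and 70.1%.

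Imprinted genes, whose control regions carry methylation on a single parental copy, had intermediate ends at a median of 49.6%. Their ends were higher at 11 of 20 (0.536 points, camera adjusted p = 0.692) and their bodies at 10 of 19 (0.108 points, camera adjusted p = 0.678). The end of H19 was at 58.2% ± 2.53 and 56.8% ± 1.44 and that of Peg3 at 44.9% ± 3.33 and 48% ± 3.7. The body of Kcnq1ot1 was at 83.5% and 83%, that of Peg13 at 45.6% and 50.4%, and that of Snrpn, with extreme values in 18 of 183 windows, at 61.5% ± 0.122 and 64% ± 1.14. Germline genes had methylated ends, with a median of 79.8%. Of these, 8 of 15 ends were higher (0.0759 points, camera adjusted p = 0.994) and 11 of 15 bodies lower (-0.483 points, camera adjusted p = 0.303), with the end of Dazl at 84.5% and 79%.

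No gene of the DNA methylation machinery passed. The end of Dnmt3a, a de novo methyltransferase, was at 69.1% ± 1.22 and 65.6% ± 2.01 (adjusted p = 0.963) and its body at 66% ± 0.376 and 66.2% ± 0.205. The end of Dnmt3b was at 32.8% ± 0.827 and 36.1% ± 0.99 (adjusted p = 0.179 when adjusted over the list alone), a difference larger than the spread within either group that did not pass, and that of the maintenance enzyme Dnmt1 at 79.5% and 80.5%. Ends of the demethylating dioxygenases lay at 32.5% and 32.1% for Tet1, 7.14% and 7.79% for Tet2 and 37.9% and 38% for Tet3. In the list 8 of 13 ends were higher (0.215 points, camera adjusted p = 0.856) and 7 of 13 bodies (0.203 points, camera adjusted p = 0.678).

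Across the lists, camera called 0 of 18 at gene ends, with 2 at an unadjusted p under 0.05, and 1 of 18 at gene bodies, with 4 at an unadjusted p under 0.05. With an estimated correlation it called 0 of 18 in both regions, and without mAdu replicate 3 it called 2 of 18 at gene bodies. Fry called 0 of 18 in both regions when asked for a shift in 1 direction, and in its mixed form it called Hox (adjusted p = 0.0023), imprinted (0.000394) and inflammation and interferon (0.0023) gene bodies. Fry was not run on simulated data, on other groupings of the samples or under the alternatives. How often its mixed form makes false calls here is therefore unknown, and these calls are no evidence of an age effect by themselves. No listed gene passed over all genes. The mean, the median and camera's direction differed in sign for several lists that did not pass. At gene ends this held for germline genes (mean 0.0759, median 0.4, camera lower), inflammation and interferon genes (-0.528, 0.149, higher) and senescence genes (-0.0118, 0.329, higher). At gene bodies it held for Hox (-0.117, -0.353, higher), lung capillary (-0.354, -0.337, higher), epithelial (-0.00209, 0.16, higher), haematopoietic (0.227, -0.0475, higher), mesenchymal (0.0611, -0.0503, higher), endothelial identity (0.101, -0.253, higher) and senescence genes (-0.0964, 0.0911, lower).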

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

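The tests without windows of extreme values, at the more methylated gene end, and with samples left out of the list tests were chosen after the result was seen. Over all results and alternatives, 189 stayed close, by direction and side of the threshold or, for counts, within 1.5 times whatever their direction, 33 counts moved by over 1.5 times, 40 values kept their direction and lost their call, and 15 values, none of them past a threshold, changed sign. The 355 windows became 145 on the logit scale, 59 without extreme values, and 680 to 998 with a sample left out. Higher windows were 42.3% of calls with all samples, 60.8% to 63.6% without an mAdu sample and 25.5% to 32.9% without an aged sample; the cause was not tested. The count of 100-kb intervals was 0 to 1 with a sample left out. The 1 gene end became 0 on the logit scale, without the variance trend, at 1000 bp and at 200 bp either side of the edge, 2 at the more methylated end, and 0 to 4 with a sample left out, where calls turned from 1 higher and 0 lower to 0 and 1 without mAdu replicate 1, 0 and 2 without mAdu replicate 3, 0 and 4 without aged replicate 1, and 1 and 2 without aged replicate 3. The 3 gene bodies became 1 on the logit scale, 1 with a robust prior, 0 without extreme values, and 0 to 3 with a sample left out. The 1 list at gene bodies became 0 with an estimated correlation and 1 to 2 with a sample left out. Aplnr kept its call over the list alone under each alternative run. These runs reuse the same samples, and the adjustment over the list alone does not correct over the 36 list tests. A member passed in this way in 2 of 18 lists at gene ends, both through Aplnr, and in 1 of 18 at gene bodies. The cause of these moves was not tested, except that removing extreme values removes windows.

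With a sample left out, the difference of the mean level ranged from -0.29 to 0.017 points. The shares ranged from 0.00467 to 0.0341 points for lowly, -0.122 to 0.834 for intermediately and -0.858 to 0.109 for highly methylated windows. Differences ranged from -0.0417 to 0.0795 points in the low class, -0.367 to 0.0114 in the intermediate class, -0.213 to 0.0265 in the high class, -0.153 to 0.0253 at gene ends, -0.225 to 0.0295 in gene interiors and -0.358 to 0.00723 outside genes. Lower autosomes numbered 6 to 19. Signs changed without aged replicate 2 in each of these measures but the share of lowly methylated windows and the count of autosomes, and also without mAdu replicate 1 (high class, gene ends, interiors), aged replicate 1 (gene ends), and mAdu replicate 3 and aged replicate 3 (low class).

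No pairing by replicate number was seen: deviations of same-numbered samples correlated at -0.0116, -0.0167 and -0.000645 across windows. Those of differently numbered samples lay between -0.00877 and 0.0202. Values this near 0 cannot show whether samples were handled in pairs. With the replicate number as a block, 185 windows, 0 gene ends and 0 gene bodies passed, and the list alone p of Il6 was 0.0918. Minimum coverage or CpG number, weighting by them, and sex chromosomes were not run, since the table used here holds none of these, and a median does not apply to shares. Accepting windows with values in at least 2 samples of each group added 0 windows and tests nothing. Depth limits are unknown. At 10 points, 1.5% of shifted single windows were recovered in simulated data, so smaller differences there would be missed.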

Other observations

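The tests of other splits of the samples for windows, intervals, gene ends and gene bodies, and those of a shift of the whole scale, of haematopoietic markers and of the spread between samples were chosen after the result was seen.

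Several gene groups had levels outside the range of random lists of genes, over all 6 samples. Shear stress and quiescence genes, which respond to blood flow, had a median of 4.32% at their ends, where 95% of random lists of equal size lay between 17.5% and 55%. The end of Klf2, a flow-induced transcription factor, was at 1.77% in mAdu and 0.805% in aged. Angiogenic signalling genes had a median of 7.94% at their ends (random lists 18.6% to 54%) and 60.3% over bodies (67.4% to 77.7%). Lung capillary bodies had a median of 51.3% (67.6% to 78.1%), and that of Calcrl, a receptor for adrenomedullin, was at 28.8% and 28.6%. Low levels were not particular to endothelial programmes: Wnt genes had a median of 15.7% at their ends (20.4% to 51.4%), TGF-beta and BMP genes 12.9% (19.2% to 52%), and bodies of genes named for age-related methylation 49.5% (65.4% to 77.5%). Germline ends lay at the other side, at 79.8% (17.8% to 56%). These are descriptions of levels, chosen after the data were seen, and not tests of age.

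Of the 355 single windows that passed, 288 held an extreme value, and the differences had a median size of 90.8 points and a smallest of 19.3. A candidate explanation is that few or ambiguously placed reads set such values. Windows whose samples span over 90 points had a median of 15 of the 20 nearest positions in the table, against 17 for all windows, although fewer of them lay where under 10 positions were filled (8.43% against 11.6%); for the 355 windows these values were 14 and 13%. Other splits of the 6 samples gave 289 to 438 windows against 355 for the real one. As many were given by 4 of 10 splits, the real one included, and 10 splits are too few for a share under 0.05. The count of 355 thus lies within the range of splits that mix the ages and is no evidence of an age effect. An effect of age on part of these windows stays open as untested, and coverage was not available to test the reads directly.

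Capillary genes were split into aerocyte and general capillary classes after their values were seen. The classes left out the listed genes Sema3c, Hpgd, Icam2, Calcrl and Ramp2 and took in Kdr from other lists. Bodies of 6 of 6 aerocyte genes were higher (2.71 points) and of 5 of 5 general capillary genes lower (-3.26 points). Over the whole lung capillary list 5 of 14 bodies were higher (camera adjusted p = 0.999). Ends in the classes were less uniform (4 of 7 higher, 5 of 6 lower). The exact p across samples was 0.2 for bodies and 0.1 for ends. Of the genes in the classes only Aplnr passed, at its end and over the list alone. The hypothesis of a shift between these cell types in the sorted cells was tested on further genes recalled as markers and not looked at before: at their ends 7 of 8 aerocyte genes were higher and 6 of 7 general capillary genes lower, a difference of 1.69 points (SE 0.675, one-sided exact p = 0.0182 across genes, which are not independent). Across samples the exact p was 0.1, the smallest it can be, and over bodies, where 5 of 7 aerocyte genes were higher and the mean change of general capillary genes was 0.102 points with 5 of 8 lower, the difference was 0.735 points (one-sided exact p = 0.139 across genes, 0.5 across samples). The median change of all gene ends was 0.0314 points. A shift of the whole scale would move both classes alike, so this value does not bear on their moving apart. The values are consistent with a change in the mix of capillary cells, and a change of methylation with age within these cells stays open as untested.

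Bodies of inflammation and interferon genes were on average lower in aged samples, and blood or immune cells among the sorted cells may contribute, as these express Cd74 and other members, while none of the haematopoietic markers is on another list. Such cells would lower the bodies of haematopoietic markers, whose mean change was 0.227 points (SE 0.207 over 13 genes) while the median was -0.0475 and 8 of 13 were lower, with Ptprc at 74% in mAdu and 74.6% in aged; the sort for endothelial cells should remove them. The bound first written against this explanation, a change at or above 0, is met, but it was moved to 2 standard errors from 0 after the value was seen, so the explanation cannot be told apart from others, as a small share would be hidden; age stays open as untested. The list call itself is lost with an estimated correlation (adjusted p = 0.32) and is not made by fry for a shift in 1 direction (adjusted p = 0.134). The estimated correlation was -0.0179, below the preset 0.01, so a stronger correlation between the genes is not what removed the call. In the other splits the smallest camera p was 0.0685 against 0.000276, 1 of 10 splits gave a p as small, and 10 splits are too few for a share under 0.05.

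Other splits gave up to 2 intervals against 0 for the real split (10 of 10 gave as many), up to 3 gene ends against 1 (6 of 10), up to 3 gene bodies against 3 (3 of 10), and 0 lists against 1 (1 of 10), and 10 splits are too few for a share under 0.05. The hypothesis of more spread between aged samples was tested by the median SD of windows, 3.1 points in mAdu and 3.07 in aged. The gap was -0.037 points, and other splits had gaps up to 0.0802. SDs of values per sample went in both directions, untested. They were 0.317 points in aged and 0.152 in mAdu for the mean level, and 0.988 and 0.414 for the share of intermediately methylated windows. For the share of lowly methylated windows they were 0.0133 in aged and 0.0314 in mAdu.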
